A study of Caenorhabditis elegans with 3 samples.

How the data were processed

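Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans larvae at the L2 stage. Per the labels, the animals belonged to strain NC1639, which carries an integrated transgene with the ttr-39 promoter, used to drive expression in GABA motor neurons, in front of UNC-55a fused to GFP, together with a dpy-20 marker. UNC-55 is the nematode member of the COUP-TF family of nuclear receptors. The 3 samples are biological replicates 1, 2 and 3 of a single group, and their replicate numbers come from the sample descriptions. The labels disagree on the tag: all 3 sample descriptions name eGFP-unc-55 as the target of the immunoprecipitation, and 1 free-text note, on replicate 3, describes a GFP-FLAG tag at the C terminus. The antibody field gives only the target, UNC-55. The labels give a fragment size range of 150 to 350 bp for replicates 1 and 2, and sonication with a microtip for replicate 3. The 3 replicates therefore differ in what is stated about their preparation, and the effect of that difference cannot be separated from replicate 3 itself.

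The authors deposited peak lists in the narrowPeak format, with coordinates in the ce11 build and again in ce10. Per the notes deposited with the files, a relaxed list meant as input to the irreproducible discovery rate (IDR) procedure was called for each replicate against 1 shared control alignment. A pooled list was called on the 3 replicates together against the same control, and an optimal list held the peaks that passed the authors' IDR threshold. The peak caller, the aligner and their versions are not given in the sources used here. The control reads were not analysed here. Each peak carries a signal value written by the authors' caller, whose relation to read depth is not stated, and the −log10 of a q-value, also as deposited. The p-value field of the format was not filled. The signal value is the authors' own and was used only to describe, rank and filter peaks within a list. No read counts accompany the lists, so the sequencing depth per replicate is unknown and no interval or detection limit that needs depth was computed. Relaxed lists contain weak calls by construction, and 4 of the 5 ce11 lists were relaxed. The lists of replicates 1 and 2 and the pooled list stopped at 30000 peaks, so their lower ends are set by that number.

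Peaks were compared in ce11, and ce10 lists served only as an alternative. Gene positions came from Ensembl release 115 and the sequence from the matching RefSeq assembly. No coordinates were converted between builds. Chromosome lengths were taken from the sequence, and the mitochondrial genome was left out. A replicate peak counted as overlapping an optimal peak when it covered at least 50% of the optimal peak's length. For comparisons between replicates, the 5993 peaks of highest signal were taken from each list, which is the size of the optimal list. Chance overlap came from 1000 shuffles of the peaks within their chromosomes. A promoter window ran from 2000 bp upstream to 500 bp downstream of any annotated transcription start site (TSS) of a protein-coding gene. The promoter share was set against 59930 random positions on the same chromosomes and against the 23511 pooled peaks that overlapped no optimal peak, with Fisher's exact test, two-sided.

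Gene lists were fixed before the data were examined, 14 by gene symbol and 11 by symbol pattern. Of 259 symbols, 4 (nca-1, efn-1, opt-2 and mir-228) matched no protein-coding gene in the annotation and were left out. A gene counted as having a peak when an optimal summit lay in its promoter window. Each list was compared with all 19973 nuclear protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 25 lists. Shares of genes carry exact (Clopper-Pearson) 95% intervals, which describe the number of genes and not sequencing depth. The text names every gene of the transgene and of the reported UNC-55 targets, up to 4 genes of highest signal for each other symbol list, the nearest-TSS gene of the 10 strongest optimal peaks, and up to 3 genes for each pattern list with an adjusted p under 0.05. Genes named outside this rule are said to be so.

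AGGTCA, the core recognised by many nuclear receptors, was searched on both strands within 50 bp of each summit and in windows of the same size centred 300 bp to either side. Summit and flank were compared with the exact McNemar test, two-sided, for each side. All 2080 hexamers, both strands joined, were ranked by the ratio of summit to mean flank frequency with 1 added to each count. The share of peaks on X was compared with the share of X in the nuclear genome by an exact binomial test. Unless said otherwise, values given as mean ± SD are over the 3 replicates, each with its own 5993 strongest peaks. Coverage of the optimal peaks and signal correlations used each replicate's whole list, and the SD of the correlations is over the 3 pairs of replicates. The labels call the samples biological replicates. Tests over peaks or genes treat these as units, and neighbouring peaks and related genes are not independent, so their p-values are descriptive.

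Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The overlap routine was tested on simulated lists, where it and bedtools 2.31.1 both counted 2404 of 5993 peaks. Of 1000 random lists of 25 genes tested against the optimal peaks, 42 had p under 0.05 and 0 had an adjusted p under 0.05. Of 1000 lists of 25 genes drawn at 6 times the odds, 99.4% were above the background with an unadjusted p under 0.05 (Fisher's exact test). Shorter lists, smaller odds and the adjusted p were not tried in this way. AGGTCA written into 328 of 5989 random-position summits ranked 1 among hexamers. This checked the counting at random positions, and not whether such a site would rank high at the real summits. Alternatives to the overlap rule, promoter window, background, motif window and peak threshold were chosen before the data were examined, as was leaving out each replicate in turn. Leaving out a replicate kept the optimal peaks found among the strongest peaks of both others, because the authors' IDR step was not rerun. Found meant overlapped under the rule above, so an optimal peak could drop out although a high-ranking replicate peak lay at it. A ce10 comparison at the transgene's genes was planned and not run, since no ce10 annotation was used here.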

Results

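The data collected were peak lists from UNC-55 ChIP-seq in L2 larvae, with 3 biological replicates in 1 group. The ce11 relaxed lists held 30000 peaks in replicate 1, 30000 in replicate 2 and 25262 in replicate 3. The pooled list held 30000 peaks and the optimal list 5993. All 5993 optimal peaks were the strongest of the pooled list by signal. They had a median width of 322 bp and signal values from 45.8 to 1225, with a median of 108.5. No peak was identical between replicate lists. With a single group and no control sample in the series, the design implies how far the replicates share peaks, and which genes and sequences the peaks lie at.

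The strongest peaks included those upstream of ribosomal protein genes. The highest signal of all, 1225, was 165 bp upstream of cdc-48.1, which encodes an AAA ATPase that acts on ubiquitylated proteins (WBGene00007352, chromosome II, peak 10563411 to 10563752, intergenic). This peak ranked 1, 1 and 5 in replicates 1, 2 and 3. The peak upstream of rpl-3, a protein of the large ribosomal subunit, followed with a signal of 1151 and ranks of 4, 2 and 1 (WBGene00004414, chromosome III, 3867391 to 3867749, intergenic, 275 bp from the TSS). The next 2 lay between rpl-20 and Y17G9B.5 (signal 1059, chromosome IV, 4749900 to 4750241) and upstream of rpl-15 (signal 1056, chromosome IV, 654739 to 655076). Peaks upstream of ska-3, K12H4.5, rpl-35 and tasp-1, all on chromosome III, had signals of 877, 840, 826 and 813. The remaining members of the 10 strongest were on X and more than 2000 bp from a protein-coding TSS, 4023 bp downstream of the start of W02H3.3 (signal 897) and 2574 bp downstream of that of F22H10.2 (signal 890). These 10 peaks ranked no lower than 31 in any replicate.

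The replicates shared most of these sites. On average 93.5% ± 2.67 of the optimal peaks (SD, n = 3) were covered by a replicate's own whole list, 96.4% for replicate 1, 92.9% for replicate 2 and 91.1% for replicate 3. Shuffled peaks gave means of 9.68%, 9.64% and 8.40%, and at most 10.9% in 1000 shuffles. The 5993 strongest peaks of a replicate covered 80.3% ± 5.58 of the optimal peaks (SD, n = 3). Between the 5993 strongest peaks of each replicate, 72.1% were shared by replicates 1 and 2, 66.7% by 1 and 3, and 68.2% by 2 and 3, against chance means of 1.69% to 1.85%. The shuffles placed peaks uniformly along their chromosome, so the chance values leave out any preference of peaks for promoters. A total of 3386 optimal peaks (56.5%) were among the strongest peaks of all 3 replicates, and 101 were among those of none. Across optimal peaks, the rank correlation of signal between replicates was 0.765 for replicates 1 and 2, 0.734 for 1 and 3, and 0.698 for 2 and 3, a mean of 0.732 ± 0.0334 (SD, 3 pairs). These correlations run across peaks, which are not independent replicates. The optimal list was itself chosen from these replicates, so its coverage by them is not independent evidence.

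Peaks were concentrated just upstream of genes. Summits in promoter windows made up 69.0% of the optimal list (4134 of 5993) and 69.5% ± 0.438 of the strongest peaks per replicate (SD, n = 3). Random positions gave 46.1% (odds ratio 2.60, Fisher's exact p = 1.56e-255) and weaker pooled peaks 44.3% (odds ratio 2.80, p = 3.47e-260). Within promoter windows, 88.1% of summits were upstream of the nearest TSS, and the median distance of all summits there was -219.5 bp (negative upstream). A window holds 2000 bp upstream and 500 bp downstream, so a high upstream share follows in part from its shape. The same share was not computed for random positions. Intergenic sequence within 2000 bp upstream of a TSS held 49.9% of optimal summits and 18.4% of random positions. Introns held 1497 optimal summits, UTRs 325 (5.42%) and coding exons 113 (1.89%), against 24.7% of random positions in coding exons. The promoter share fell with signal, from 84.5% in the strongest of 10 equal bins to 50.4% in the weakest, and GC content at the summit fell from 47.7% to 40.1%.

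**Figure D1:**
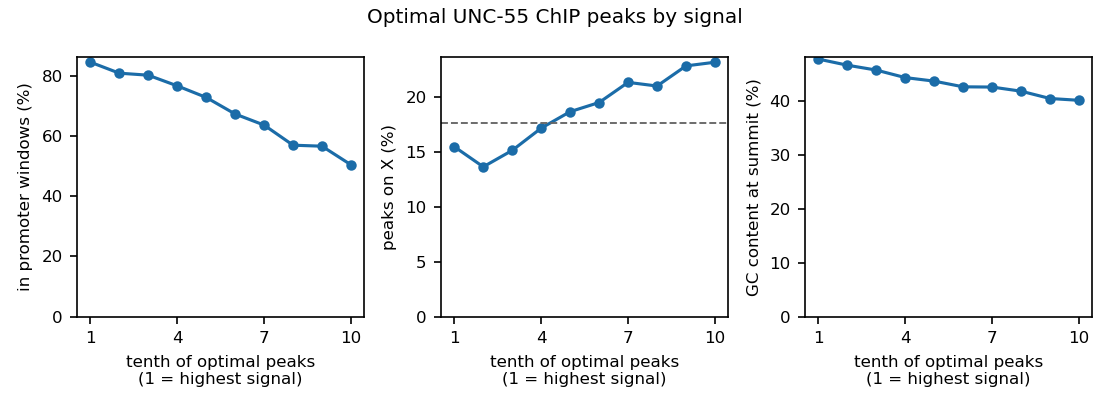
Optimal peaks split into 10 equal bins by falling signal (x axis), with the percentage of summits in promoter windows (left), of peaks on X (middle, dashed line at the X share of the genome, 17.7%) and the GC content of the 101 bp at the summit (right). From the strongest to the weakest bin the promoter share went from 84.5% to 50.4% and the X share from 15.5% to 23.2%.

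Of the 25 gene lists, ribosomal protein genes and pan-neuronal genes carried peaks most often. A peak lay in the promoter window of 76 of 81 ribosomal protein genes (93.8%; 95.1% in each of the 3 replicates), led by rpl-3, rpl-20 and rpl-15. Pan-neuronal genes, which serve synaptic vesicle release and neuropeptide processing in nearly all neurons, had peaks at 23 of 24 members (95.8% ± 4.17, SD, n = 3 replicates). Among them were the synaptic vesicle GTPase gene rab-3 (signal 361, intron, chromosome II, 5725082 to 5725482), the proprotein convertase gene egl-3 (signal 355, intergenic, chromosome V, 10174593 to 10175032), rgef-1 (signal 322, intergenic, chromosome V, 9561708 to 9562262) and the carboxypeptidase gene egl-21 (signal 284, intergenic, chromosome IV, 10481704 to 10482048). For comparison, 25.5% of all protein-coding genes (5094 of 19973) had a peak, and 25.9% ± 0.202 in the replicates (SD, n = 3). The odds ratios were 45.1 for ribosomal protein genes (adjusted p = 4.02e-38, Fisher's exact test) and 67.5 for pan-neuronal genes (adjusted p = 3.28e-12). The lower ends of the exact 95% intervals were 86.2% and 78.9%. Both calls held in every alternative, with ribosomal odds ratios from 5.06 when each peak was given to its nearest TSS alone (42 of 81 genes) to 60.2, and pan-neuronal ones from 6.51 without replicate 3 (15 of 24) upwards. With gene bodies added, 24 of 24 pan-neuronal genes had a peak, so that this odds ratio has no finite value. Without replicates 1, 2 and 3 in turn, the ribosomal odds ratio was 15.3, 23.6 and 20.7, and without replicates 1 and 2 the pan-neuronal one was 10.5 and 12.2. In the replicates' own strongest peaks, 24, 23 and 22 of 24 pan-neuronal genes had a peak. The lower values without a replicate therefore do not show that peaks were missing from one.

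Genes of neuronal signalling and wiring and of muscle also exceeded the genome's share. cAMP and G protein signalling genes had peaks at 16 of 23 members, including the Gq alpha subunit gene egl-30 (signal 509, rank 61 of the optimal list, chromosome I, 1835465 to 1835758), the adenylyl cyclase gene acy-1 (signal 324), the Gs alpha subunit gene gsa-1 (signal 246) and ric-8 (signal 238). Axon guidance genes had peaks at 12 of 21, the same number in each replicate, led by the netrin receptor gene unc-40 (signal 274, chromosome I, 5691625 to 5691905), unc-51, unc-76 and unc-44. Body wall muscle genes had peaks at 13 of 28 (46.4% ± 3.57, SD, n = 3), among them unc-112 (signal 278), the acetylcholine receptor subunit gene unc-63 (signal 254), the myosin chaperone gene unc-45 (signal 221) and the GABA receptor gene unc-49 (signal 176). Members of the muscle list without a peak, named here outside the rule, included hlh-1, myo-3, unc-15, unc-22 and unc-54. For the signalling, axon guidance and muscle lists, the odds ratios were 6.69 (adjusted p = 4.09e-05), 3.90 (adjusted p = 0.00505) and 2.54 (adjusted p = 0.0365, Fisher's exact tests). All 3 calls ended when the background was restricted to genes with a pooled-list summit (adjusted p = 0.310, 0.718 and 0.718, Fisher's exact tests), and the cAMP odds ratio was 4.26 without replicate 3. The axon guidance call also ended without replicate 1 (8 of 21 genes, odds ratio 2.66, adjusted p = 0.0987) and without replicate 2 (9 of 21, 3.04, 0.0580), and held without replicate 3 (11 of 21, 4.29, 0.00359, Fisher's exact tests). It ended among the 2996 strongest peaks too (5 of 21, odds ratio 1.47, adjusted p = 0.465, Fisher's exact test). The muscle call ended without replicate 1 (7 of 28 genes, odds ratio 1.44, adjusted p = 0.528), 2 (8 of 28, 1.62, 0.315) or 3 (8 of 28, 1.56, 0.404, all Fisher's exact tests) and among the 2996 strongest peaks (0.256). Leaving out a replicate kept only optimal peaks overlapped by the strongest peaks of both others. In the replicates' own strongest peaks, 13, 14 and 12 of 28 muscle genes had a peak, and 12 of 21 axon guidance genes in each. The calls lost by leaving out a replicate therefore do not show that they rested on that replicate. The axon guidance and muscle calls both ended with the window of 1000 bp upstream to 200 bp downstream (0.405 and 0.544, Fisher's exact tests). Against random lists matched on window length and GC content, a comparison chosen after the counts were seen, axon guidance genes (12 against a mean of 7.03) and muscle genes (13 against 9.82) did not pass either (adjusted permutation p = 0.0586 and 0.321).

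UNC-55 is known to keep the synapses of ventral D GABA motor neurons from being remodelled. Whether peaks lay at genes of GABA neurons was asked with a list fixed beforehand. It covers GABA neurons in general, so it does not test genes of ventral D neurons alone. Of 16 GABA neuron genes, 6 had a peak (37.5%; 35.4% ± 3.61 in the replicates, SD, n = 3). Those of highest signal were at the calcium sensor gene ncs-2 (signal 307, chromosome I, 10035029 to 10035324) and the vesicular GABA transporter gene unc-47 (signal 278, chromosome III, 10187990 to 10188256, 1857 bp upstream). Next came the homeobox gene unc-30, which specifies D-type GABA motor neurons, dorsal and ventral (signal 222, chromosome IV, 13118787 to 13119084), and gta-1 (signal 144). No difference from all genes was detected (odds ratio 1.75, adjusted p = 0.336, Fisher's exact test; 95% interval of the share 15.2% to 64.6%). The count fell to 2 of 16 without replicate 1 (odds ratio 0.616) and to 1 of 16 without replicate 3 (odds ratio 0.259). The odds ratio was 0.832 against genes with a pooled-list summit, so that its direction depends on these choices. Yet the peaks at ncs-2, unc-47, unc-30 and gta-1 ranked among the 5993 strongest of every replicate, at 5312 or better. The falls therefore do not show that these peaks were missing from a replicate. Leaving out a replicate dropped optimal peaks by the overlap rule. Because these peaks ranked among the strongest of both other replicates, the falls came at least in part from that rule. Cholinergic motor neuron genes had peaks at 2 of 17, the co-repressor gene unc-37 (signal 292) and the T-box gene mab-9 (signal 69.0), and no difference was detected either (odds ratio 0.389, adjusted p = 0.336, Fisher's exact test). Without replicates 1, 2 and 3 in turn the count was 0, 1 and 0 of 17. The unc-37 peak nevertheless ranked 436, 903 and 278 in replicates 1, 2 and 3. These counts therefore do not show that it was missing from a replicate. Tested directly, GABA neuron genes had peaks less often than pan-neuronal genes (Fisher's exact p = 8.50e-05, adjusted p = 0.000340 over 4 comparisons chosen after the counts were seen), and no difference was detected from cholinergic genes (p = 0.118, adjusted p = 0.157) or from body wall muscle genes (6 of 16 against 13 of 28, p = 0.753, adjusted p = 0.753, Fisher's exact tests).

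Among the 6 genes described before as regulated by UNC-55, 2 had an optimal summit in a promoter window (2, 3 and 3 in replicates 1, 2 and 3; 44.4% ± 9.62, SD, n = 3). At oig-1, which encodes an immunoglobulin-domain protein that restrains synapse remodelling, the peak lay 907 bp upstream (signal 127, rank 2512, chromosome III, 6526508 to 6526666, intergenic). At the phosphodiesterase gene pde-4, it lay in an intron 176 bp upstream of an internal TSS (signal 165, rank 1738, chromosome II, 7642156 to 7642477). The transcription factor gene hbl-1 had no optimal summit in its window, but 3 intergenic peaks lay 2103, 4758 and 5728 bp upstream on X with signals of 123, 158 and 156, the nearest just outside the window. No optimal summit lay within 6000 bp of flp-13, unc-8 or irx-1, although irx-1, like hbl-1, had a pooled-list summit in its window. No difference from all genes was detected (odds ratio 1.46, Fisher's exact p = 0.649, adjusted p = 0.649; 0.694 against genes with a pooled-list summit), and with 6 genes the 95% interval of the share ran from 4.33% to 77.7%. Compared directly, these genes had peaks less often than pan-neuronal genes (Fisher's exact p = 0.00257, adjusted p = 0.00514 over the same 4 comparisons).

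Chemoreceptor, F-box, nuclear hormone receptor, cuticle collagen, neuropeptide-like protein and major sperm protein genes carried peaks less often than the genome. Chemoreceptor genes had peaks at 28 of 1237 members (2.26%; odds ratio 0.0625, adjusted p = 2.29e-118, Fisher's exact test), with sri-5, srh-16 and srg-55 the strongest; the srg-55 peak ranked 24524 in replicate 2 and 336 and 851 in replicates 1 and 3. F-box genes had peaks at 31 of 322 (odds ratio 0.307, adjusted p = 3.82e-12, Fisher's exact test), led by fbxb-58 (signal 742, X, 1626879 to 1627417), fbxb-85 and fbxa-90. Nuclear hormone receptor genes, the family of unc-55 itself, had peaks at 32 of 269 (odds ratio 0.391, adjusted p = 2.10e-07, Fisher's exact test), led by nhr-47, nhr-1 and nhr-142. Cuticle collagen genes had peaks at 13 of 156 (odds ratio 0.264, adjusted p = 3.49e-07; col-38, col-94 and col-72), neuropeptide-like protein genes at 6 of 71 (odds ratio 0.269, adjusted p = 0.00145; nlp-71, nlp-12 and nlp-4) and major sperm protein genes at 0 of 31 (adjusted p = 0.000710, all Fisher's exact tests). With the window of 1000 bp upstream to 200 bp downstream, 9 chemoreceptor genes (odds ratio 0.0274) and 1 neuropeptide-like protein gene (odds ratio 0.0574) had peaks. Against genes with a pooled-list summit, the chemoreceptor odds ratio was 0.310, the neuropeptide one 0.129 and the F-box one 1.02 (adjusted p = 1, Fisher's exact test). Only 1 major sperm protein gene had such a summit, so that call could not be kept against this background (0 of 1, adjusted p = 0.683, Fisher's exact test). The neuropeptide call ended without replicate 1, where the count was still 6 of 71 (odds ratio 0.397, adjusted p = 0.0554, Fisher's exact test). The replicates' own strongest peaks gave 5, 6 and 6, so the lost call does not show that the low share rested on replicate 1.

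The remaining lists had an adjusted p of 0.05 or more against all genes with the window of 2000 bp upstream to 500 bp downstream. They were pharyngeal genes (1 of 16, phat-3), intestinal genes (3 of 25: vha-6, erm-1 and gem-4), epidermal genes (4 of 26: wrt-1, sqt-1, elt-1 and dpy-8), germline genes (2 of 23: nos-3 and spn-4), vulval and gonadal genes (2 of 14: lin-39 and egl-17) and glial genes (0 of 13, adjusted p = 0.0870, Fisher's exact test). Histone genes had peaks at 11 of 72, homeobox genes named ceh at 12 of 63, FMRFamide-like peptide genes at 3 of 31 (adjusted p = 0.0777) and acetylcholine receptor subunit genes named acr at 1 of 21 (adjusted p = 0.0508, Fisher's exact tests). Some of these lists fell below the background under other settings, namely glial and histone genes with gene bodies added (adjusted p = 0.0498 and 0.0488), FMRFamide-like peptide and acr genes against genes with a pooled-list summit (0.0227 and 0.0354) and acr genes without replicate 3 (0.0295, all Fisher's exact tests), and histone genes against lists matched on window length and GC content (adjusted permutation p = 0.0408). Against genes with a pooled-list summit, epidermal and histone odds ratios turned from 0.531 and 0.526 to 2.78 and 1.09 (adjusted p = 0.861 and 1, Fisher's exact tests). The strongest peak among the tissue lists of this group was that of nos-3, a germline translational regulator, with a signal of 403 (chromosome II, 9746131 to 9746385).

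**Figure D2:**
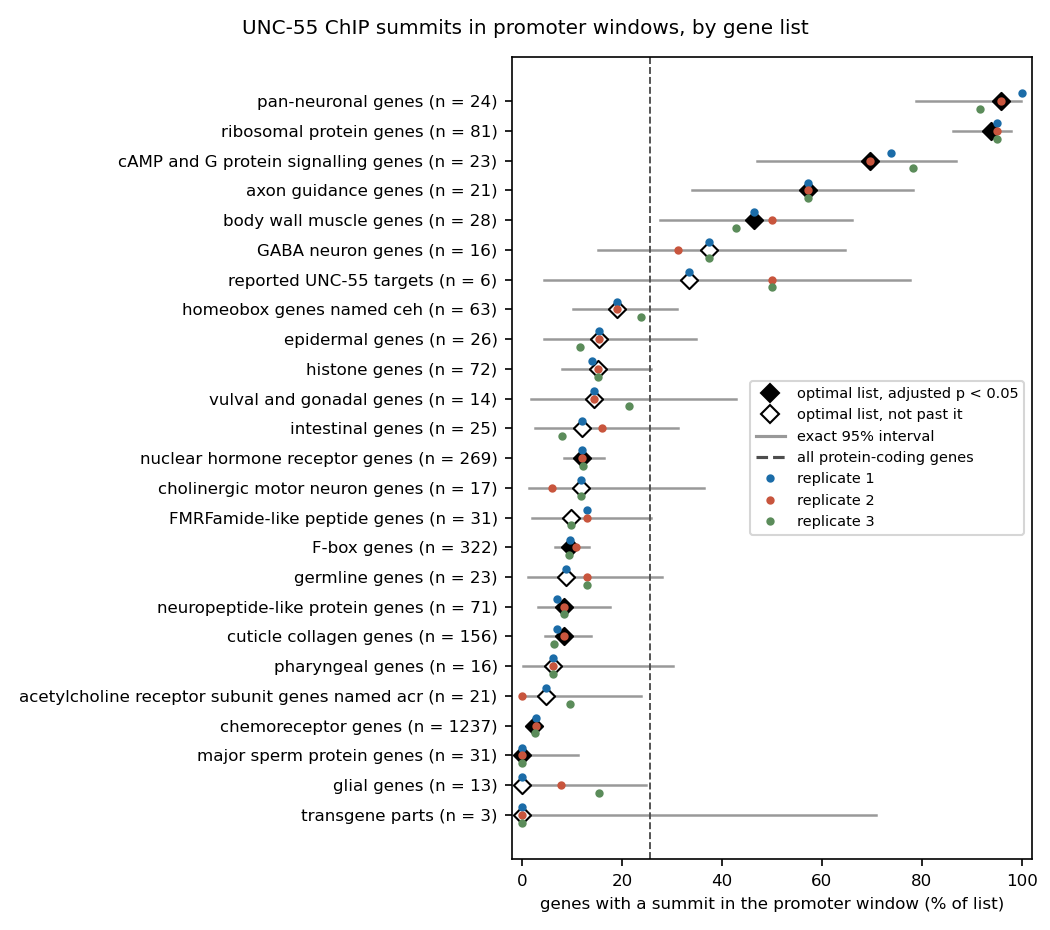
Percentage of each gene list with a summit in the promoter window (x axis) for the 25 lists (y axis). Diamonds are the optimal list, filled where the adjusted p was under 0.05, grey lines are exact 95% intervals over genes, small points are the 3 replicates and the dashed line is the 25.5% of all protein-coding genes; pan-neuronal and ribosomal protein genes stand at 95.8% and 93.8%, and chemoreceptor genes at 2.26%.

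AGGTCA was not enriched at the summits. It occurred within 50 bp of 82 of 5993 optimal summits (1.37%) and in 2.64% of flanking windows, a ratio of 0.519 (exact McNemar p = 1.91e-05 against the left flank and 2.47e-08 against the right). In the replicates it was at 1.48% ± 0.0632 of summits and 2.55% ± 0.0584 of flanks (SD, n = 3), so that the difference exceeded the spread between replicates. AGGTCA ranked 1909 of 2080 hexamers. All 15 hexamers of highest ratio contained CG, from GCGCGC (6.41% of summits, 0.642% of flanks) and AGCGCG to GACGCA (14.8% and 1.97%) and ACGCAG. Longer elements were then chosen from these ranks and counted on the same summits, so their frequencies are descriptive and no independent support. GAGACGCA was within 50 bp of 9.18% of summits and in 0.551% of flanks (8.32% ± 0.246 of summits in the replicates, SD, n = 3), and AAGTGCGC at 2.89% and 0.117%, rising to 13.4% and 7.18% of the 599 strongest peaks.

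**Figure D3:**
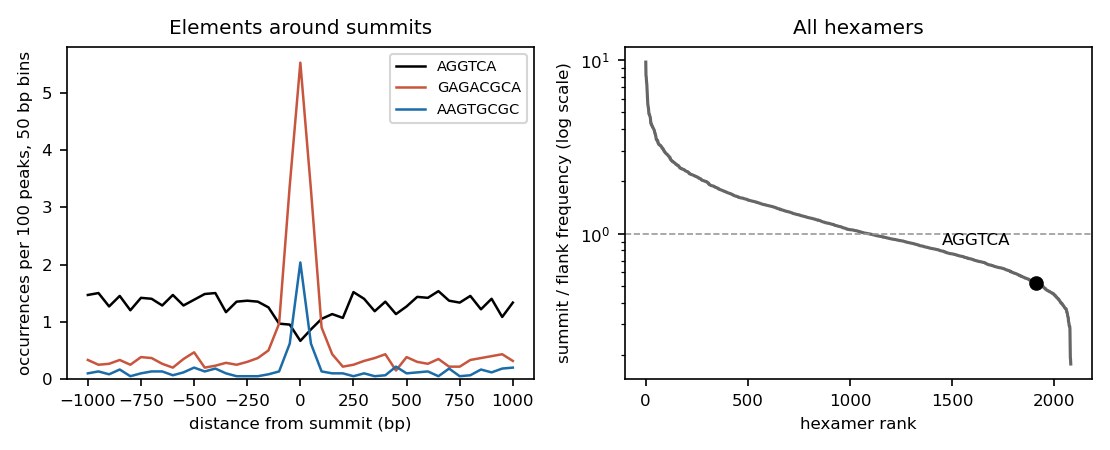
Left, occurrences per 100 optimal peaks in 50 bp bins (y axis) by distance from the summit in bp (x axis) for AGGTCA and for 2 elements chosen after the hexamer ranks were seen. Right, summit over flank frequency (log axis) of all 2080 hexamers by rank, with AGGTCA marked at 0.522 and rank 1909; GAGACGCA and AAGTGCGC peak at the summit, where AGGTCA has its lowest bins.

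X held 1128 of the optimal peaks (18.8%; exact 95% interval 17.8% to 19.8%), and 18.8% ± 0.257 in the replicates (SD, n = 3), against 17.7% of the genome (exact binomial p = 0.0203). Chromosome III was the densest, with 78.6 peaks per Mb, followed by I with 73.4 and X with 63.7, and V was the sparsest with 40.2. X peaks were more often outside promoter windows (43.3%, 488 of 1128) than autosomal peaks (28.2%, 1371 of 4865, odds ratio 1.94, Fisher's exact p = 6.00e-22), and in the replicates the shares were 40.8% ± 0.690 and 28.1% ± 0.452 (SD, n = 3). The share of random positions was not split by chromosome here, so how often any position on X lies outside is not known. Weaker peaks were also both more often on X and less often in promoter windows. The excess on X changed sides among the 2996 strongest peaks, where X held 16.1%, below its share of the genome (exact binomial p = 0.0202). Without replicates 1, 2 and 3 in turn the share was 17.7%, 17.8% and 18.3% (exact binomial p = 0.932, 0.852 and 0.292), and weaker pooled peaks had 19.04% on X.

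The transgene carries parts of unc-55, ttr-39 and dpy-20, so the endogenous genes were examined for signal. No peak of the pooled list or of any replicate list lay in unc-55 (WBGene00006790, chromosome I, 7898434 to 7903334), ttr-39 (WBGene00007304, chromosome IV, 10088367 to 10089877) or dpy-20 (WBGene00001079, chromosome IV, 11696430 to 11700852), in the 2000 bp upstream of them or within 5000 bp on either side. Of all protein-coding genes, 29.9% had no peak in the gene and 2000 bp upstream in any of these lists. The stretch without any peak measured 44127 bp around unc-55, 40992 bp around ttr-39 and 31548 bp around dpy-20. Of all genes, 4.94%, 5.67% and 9.30% lay in a stretch at least as wide, and of the genes with as many pooled peaks within 60 kb 0.102%, 2.04% and 2.16% did. In the pooled list alone the stretches measured 64354, 46188 and 56837 bp, and 15.24%, 23.27% and 17.96% of all genes lay in one as wide. The search within 5000 bp and the measures of peak-free stretches were chosen after the lists were seen. The peaks were called against a control whose reads were not analysed here, so the lists do not show whether copies of these parts in the control removed signal there.

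**Figure D4:**
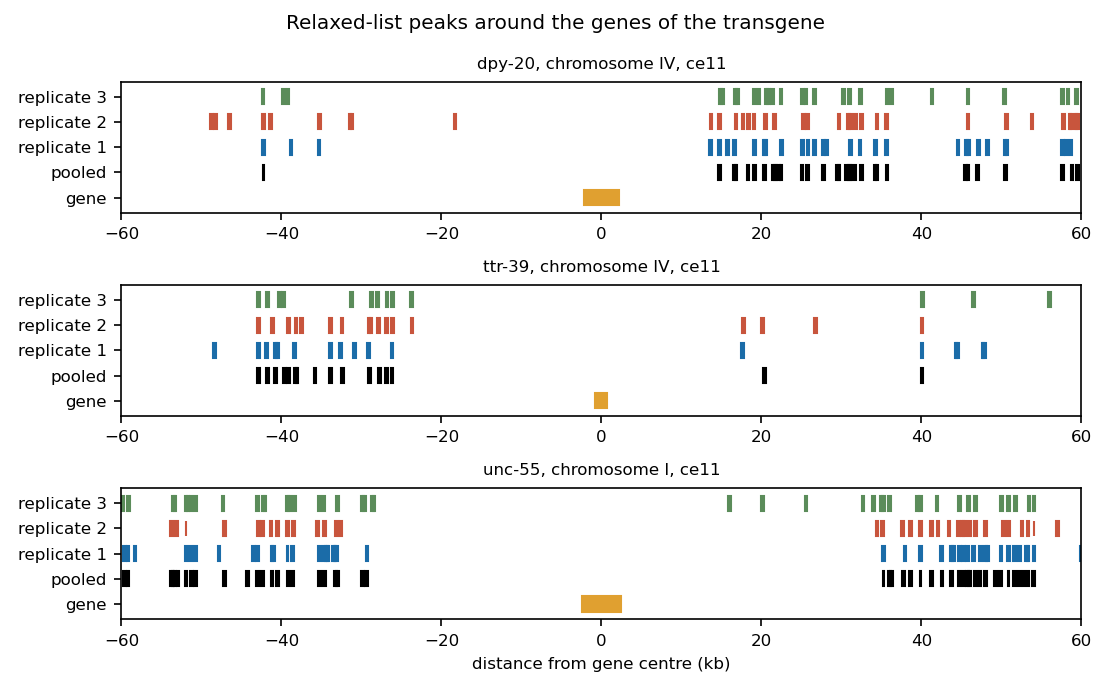
Peaks of the pooled list and of the 3 replicate lists within 60 kb of the centre of dpy-20, ttr-39 and unc-55 (x axis, kb; each gene drawn as an orange bar). No list has a peak at the genes, and the peak-free stretches around them span 31548, 40992 and 44127 bp.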

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

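The alternatives were chosen before the data were examined, except the matched gene lists, the 5000 bp region, the peaks outside promoter windows and the X share of weaker pooled peaks, which were chosen after seeing the data. The mean share of optimal peaks covered by a replicate's whole list was 98.6% when 1 bp of overlap sufficed and 97.8% for summits within 200 bp, and the shared strongest peaks rose to 78.7% and 77.4%. Without each replicate in turn the shared strongest peaks ranged from 66.7% to 72.1%. The rank correlation was 0.773 at 1 bp of overlap and 0.644 among the 2996 strongest peaks, and ranged from 0.698 to 0.765 without each replicate. The promoter share, the AGGTCA ratio (0.413 to 0.648) and the absence of peaks at the transgene's genes kept their direction and call under every alternative run for them. The number of lists above the genome's share was 5, and 3 with the 1000 bp window, 2 against genes with a pooled-list summit, 3 among the 2996 strongest peaks, 3 against matched lists, and 3 to 4 without each replicate, which leaves 3741 to 4177 peaks. Lists below it numbered 5 to 8 throughout. Of 192 list odds ratios over 24 lists and 8 settings, 166 kept their direction and call, 14 lost the call on the same side of 1, 5 gained one, and 7 changed side of 1. Against genes with a pooled-list summit, F-box genes turned to 1.02 and also lost their call, histone genes to 1.09, epidermal genes to 2.78, GABA neuron genes to 0.832 and reported UNC-55 targets to 0.694. Without each replicate the GABA odds ratio ranged from 0.259 to 1.84. The peaks at ncs-2, unc-47, unc-30 and gta-1 were among the 5993 strongest of every replicate by rank. The low GABA values therefore do not show that these peaks were missing from a replicate. The X share fell to 16.1% among the 2996 strongest peaks, was 18.8% against an expectation of 19.04% from weaker pooled peaks, and ranged from 17.7% to 18.3% without each replicate; the cause was not tested. Depth could not be assessed, as the lists carry no read counts.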

Other observations

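Further gene families were chosen after the first counts were seen, and some lay above and some below the genome's share. Peaks lay at 29 of 33 proteasome subunit genes (87.9%, odds ratio 21.3, adjusted p = 4.65e-13 over 12 families, Fisher's exact test), 16 of 20 vacuolar ATPase genes (adjusted p = 2.05e-06), 20 of 32 aminoacyl-tRNA synthetase genes (62.5%, adjusted p = 3.26e-05), 6 of 8 chaperonin genes (adjusted p = 0.00594), 8 of 12 complex I subunit genes (adjusted p = 0.00477) and 12 of 22 genes named hsp (adjusted p = 0.00594). C-type lectin genes, many of them used in immunity, had peaks at 9 of 240 (3.75%, adjusted p = 1.68e-18), UDP-glucuronosyltransferase genes at 4 of 67, cytochrome P450 genes at 7 of 74 and insulin-like peptide genes at 2 of 38 (adjusted p = 0.000139, 0.00149 and 0.00399, Fisher's exact tests). Innexin genes (3 of 24) and genes named set (13 of 31) did not pass (adjusted p = 0.166 and 0.0658, Fisher's exact tests).

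tRNA and snoRNA genes were also near summits. Of 612 tRNA genes, 201 (32.8%; 30.9% ± 1.96 in the replicates, SD, n = 3) had an optimal summit within 200 bp, against a mean of 17.3 and at most 31 in 100 shuffles. Of the 338 tRNA genes whose midpoint lay outside every protein-coding promoter window, 103 did, against at most 19. snoRNA genes had one at 79 of 346, against at most 20. snRNA genes had one at 11.6% (15 genes), against at most 10 genes, but at 4 of the 66 outside promoter windows, within the shuffled range of at most 6, and rRNA genes at 0 of 20. Pseudogenes had one at 41 of 2128, against a shuffled mean of 203, and miRNA genes at 12 of 261, within the shuffled range. At the transgene's genes, in a count chosen after the lists were seen, 81 of 100000 random gene triples (0.0810%) had all 3 peak-free stretches at least as wide as 31548 bp, while the genome held 160 such stretches; copies of these parts in the control, whose reads were not analysed here, were not examined.

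For the patterns below, the tests of promoter position and of the GCGCAGGG element were chosen after the result was seen, as was the number of 40 X summits, and how to read the comparison of noncoding starts was settled after its value was seen. No biological explanation that needs a comparison of groups was tested, because the series has 1 group, and chromatin that gives signal whatever the target was not tested.

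AGGTCA was rarer at summits than beside them, with a ratio of 0.522 when 1 is added to each count. A restriction to promoters as the cause is argued against by the 1859 peaks outside promoter windows, where the ratio was 0.564 (exact McNemar p = 0.0152 and 0.00728). Base content of the summits may account for it: of the other hexamers made of the same letters without CG, 8.40% had a lower ratio, and their ratios ran from 0.189 to 2.12 around a median of 0.951. AGGTCA therefore lay low in that range but inside its 5th to 95th percentile, from 0.461 to 1.73.

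Ribosomal protein and pan-neuronal promoters carried peaks far above the genome's share. Promoter window length and GC content are argued against as the whole cause: in 10000 random lists matched on both, at most 18 of 24 genes carried a peak where pan-neuronal genes had 23, and at most 40 of 81 where ribosomal protein genes had 76 (permutation p = 0.0002 for each, two-sided, the smallest that these draws can give). Chromatin that gives signal whatever the target could also produce this pattern, along with the 32.8% of tRNA genes near a summit. It cannot be told apart from binding by UNC-55, because no immunoprecipitation without the tagged protein was analysed here.

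The strongest X peaks included ones more than 2000 bp from any protein-coding TSS, such as those near W02H3.3 (900 bp wide, X, 11093698 to 11094597), F22H10.2 (637 bp) and, chosen after their values were seen, K02D3.1 (675 bp) and Y41G9A.17 (1040 bp, intron). Repeated sequence that collects reads is argued against only as a difference between X and autosomal peaks. Soft-masked bases made up 16.5% of the 201 bp at the 40 strongest X summits outside promoter windows. At the 40 strongest autosomal ones they made up 24.9% (permutation p = 0.0373, two-sided), and the median peak widths were 363 bp on X and 340.5 bp on autosomes. Both sets were picked for high signal and the genome's share is not given, so repeats acting at both cannot be told. Sites with the X-enriched GCGCAGGG element, a core of the motif known at recruitment sites of the dosage compensation complex, are a candidate explanation for a part of the X peaks. The element lay within 100 bp of 8 of the 40 X summits (exact 95% interval 9.05% to 35.6%) and of 0 of the 40 autosomal ones (Fisher's exact p = 0.00531), and of 8, 10 and 9 against 0 in the replicates' own lists, which leaves 32 X summits without it. Unannotated or noncoding transcription starts stay open too. Of the 40 X summits, 20 lay within 2000 bp of a noncoding gene start, against 30.5% of summits in promoter windows and 13 of 40 autosomal ones (Fisher's exact p = 0.173). The share of random X positions that near such a start is not given, so the count does not decide the question.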
